A study of Saccharomyces cerevisiae with 24 samples.

How the data were processed

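Chromatin of budding yeast was measured in 8 groups of 3 biological replicates, 24 arrays in all: WT (BY4741) and set2Δ, each with IPs of H3K9ac, H3K56ac, H4K12ac and H3. Per the labels, IP DNA was labelled with Cy5 and input DNA with Cy3, after linear amplification by transcription with T7 polymerase, and no array carried the dyes the other way. Each array held 41775 probes of 45 to 60 bases, at a median spacing of 257 bp, and 3444 control spots.

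Per the file headers, the deposited scanner files were made with Agilent Feature Extraction 10.5.1.1. Their processed signals are intensities, background-subtracted, detrended and dye-normalized with 1 linear factor per channel. They also give, per the file headers, the mean intensity of each spot and the median intensity of its local background. The deposited table of the series holds log2 ratios of IP over input, not centred. This was read from the values, which matched the log2 ratio of the processed signals (lowest correlation 0.999, slopes 0.995 to 1.0) and had column medians from -0.241 to 0.175. Positions are those of build sacCer1, per the file headers. A reference table of genes was used for names and for the lengths called coding lengths below alone. At 97.05% of the loci this length was a multiple of 3, so at the others it was not that of a coding sequence. The median of the ribosomal protein list, 842 bp, is not a multiple of 3, so its matching and adjustment for length used such lengths too.

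The log2 ratio of processed IP over input signal was taken per probe. Spots marked as outliers were left out. A probe was kept where the input was well above background on at least 2 of 3 arrays of every group, which left 41650 probes. Each array was centred on its median probe. The value of an ORF was the mean over probes inside it, with at least 2 probes, which gave 5006 ORFs. Promoters reached 500 bp upstream of the start codon and 3' flanks 250 bp downstream, and ORFs were divided into 5', middle and 3' parts of equal length. Gradients used the ORFs with a probe in each of the 3 parts, and ORF minus promoter differences those with a promoter probe. The input level in the strain check was the log2 input signal relative to the array median. The share of probes well above background was taken as the depth of an array.

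ORFs were compared with limma 3.58.1 in R 4.3.3 (package data.table, version 1.17.8), as cell means over the 24 arrays (16 residual degrees of freedom) with 7 contrasts: set2Δ minus WT for each IP, and the difference between each acetylation and H3 in that change. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the ORFs of a contrast, and the threshold was 0.05. Changes of regions were computed per array and tested by exact permutation of the strain labels, whose smallest p for 3 against 3 arrays is 0.1. Acetylation against H3 was tested by relabelling the arrays of 1 strain and number together, since they varied together, which gives 20 relabellings and a smallest p of 0.1; this test was chosen after seeing the data. Files were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.

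Gene lists were fixed before the data were examined, as were the design, the rule for named genes and most of the alternatives. The 17 lists were cryptic initiation, pheromone response, a-specific, alpha-specific, histone genes, chromatin factors, glycolysis, heat shock and chaperones, glucose-repressed, meiosis and sporulation, G1/S, G2/M, ribosome biogenesis, respiration, amino acid biosynthesis, ribosomal proteins and subtelomeric ORFs. The list of histone genes had 1 measured member and was not tested, so 16 lists and 7 contrasts made 112 tests with camera, run on the 4970 ORFs with a value on every array. Camera used a preset correlation between genes of 0.01, and again a correlation estimated from the data. Medians were set against 10000 random lists matched for length. Subtelomeric ORFs were those with a midpoint within 20000 bp of the first base or of the last probe of a chromosome, since no chromosome lengths were at hand.

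Named genes were, per IP, the 8 largest increases and 8 largest decreases among called ORFs whose arrays did not overlap between strains, for each acetylation relative to H3 the 4 largest in each direction, and up to 3 members per list with the largest change. All members of the cryptic initiation list and SET2 were also open to naming. SET2 and the auxotrophic markers were left out of rankings and lists. The 2 strains were not paired by replicate number. Within a strain, the arrays of H3K9ac, of H4K12ac and of H3 that carry 1 number varied together (correlation of deviations across probes 0.106 to 0.728 for H4K12ac with H3, and 0.234 to 0.613 for H3K9ac with H3). The inputs did so too: on 12 of 12 WT arrays and 10 of 12 set2Δ arrays the input correlated best with an array of the same number. Arrays of 1 strain and number were therefore not independent across IPs, while the main limma and camera tests treated all 24 as independent. The 16 residual degrees of freedom may thus be too many, and the IPs are not separate replicates of each other. The lowest correlation between any 2 arrays was -0.405, between H3 and H3K56ac arrays of WT. Since the labels state the dyes of both channels, the direction of the ratio was kept.

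The procedure was tested on simulated data with changes added to ORFs of 1 IP. It called 72 of 100 ORFs shifted up or down by 0.5 and 97 of 100 shifted by 1, with 14 unshifted ORFs called, and 0 ORFs in an IP with no shift. A gradient change of 0.3 was returned as 0.302. The simulated noise was independent between arrays and between ORFs or probes, and only 200 of 4970 ORFs were shifted. Arrays that vary together, a narrower range in 1 strain and changes at most ORFs, as in the data, were therefore not covered. Alternatives changed 1 choice at a time: background correction by normexp with an offset of 50, loess within arrays, no centring, centring on probes outside ORFs, scaling to 1 median absolute deviation, quantile normalization within an IP, filters on dim or marked spots, only probes with a value on all arrays of an IP, the values of the series table, the median over probes, the minimum number of probes, only ORFs of at least 1000 bp, moderation with trend, blocks for replicate number or scan, adjustment for ORF length and leaving out each array. Probes that match several places in the genome were not removed, because no genome sequence was used.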

Results

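Histone acetylation and histone H3 were mapped along the genome of budding yeast, Saccharomyces cerevisiae, in a wild-type strain (WT, BY4741) and in a strain lacking SET2 (set2Δ). SET2 encodes the methyltransferase that modifies H3K36 on transcribed genes. Chromatin was immunoprecipitated (IP) with antibodies to H3K9ac, H3K56ac, H4K12ac and H3, and each IP was hybridised against its input DNA on a tiling array of 41775 probes. The 24 arrays formed 8 groups, 1 for each strain and antibody, with 3 biological replicates per group. Per the labels, cultures in rich medium at an optical density of 0.6 received the mating pheromone a-factor at 1 mM for 4 h before crosslinking. BY4741 is a MATa strain and MATa cells respond to alpha-factor, so which pheromone was added is in doubt. The input signal was well above background at 99.4% to 99.9% of the probes of an array, and the IP signal at 96.1% to 99.9%. On the 3 set2Δ H3K9ac arrays 12.1% to 13.0% of the spots were marked as outliers by the scanner software, against at most 0.345% on any other array, and these spots were left out. The number of arrays, 3 per group, limits the precision of every value.

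The SET2 gene was near background in the input DNA of set2Δ and present in that of WT. Over its 7 probes (YJL168C, chromosome 10, 102375 to 104178, build sacCer1), the log2 input relative to the array median was -0.20 ± 0.14 (SD, n = 12 arrays) in WT and -6.87 ± 1.61 in set2Δ. All 84 WT spots and 36 of 84 set2Δ spots were well above background. On single arrays the level ranged from -0.56 to 0.05 in WT and from -9.28 to -4.27 in set2Δ, so every array carried the strain its label gives. The auxotrophic marker genes HIS3, LEU2, MET17 and URA3 were at -4.75 or lower on average in the inputs of both strains. BAR1 (YIL015W, chromosome 9, 322565 to 324053), which encodes the protease that degrades the mating pheromone alpha-factor, was at -8.10 ± 1.19 in WT and -8.17 ± 1.68 in set2Δ. BAR1 was named after its values were seen.

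A search of the inputs for runs of at least 3 neighbouring probes that were lower in set2Δ by over 2 on the log2 scale gave 2 runs. The first was SET2 itself. The second lay on chromosome 9 beside BAR1, at 324768 to 336218, and covered 40 probes and 6 genes: YIL014C-A, MNT3, PDR11, TIR3, DOT5 and EST3. Its median input difference was -6.69. Of the set2Δ spots 26 of 72 at MNT3, 89 of 180 at PDR11, 17 of 48 at DOT5 and 16 of 36 at EST3 were well above background. The counts were 31 of 36 at TIR3 and 12 of 12 at YIL014C-A. The size of the difference is therefore uncertain, and that of SET2 was -1.92 with normexp background correction. The mean over the stretch ranged from -0.46 to -0.04 on the WT arrays and from -9.23 to -3.96 on the set2Δ arrays. These loci were singled out after their values were seen, and IP values within the stretch rest on an input far below the array median in set2Δ. The strains thus differ at this stretch as well as at SET2, and the changes below are differences between the strains that cannot be assigned to SET2 alone.

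**Figure D1:**
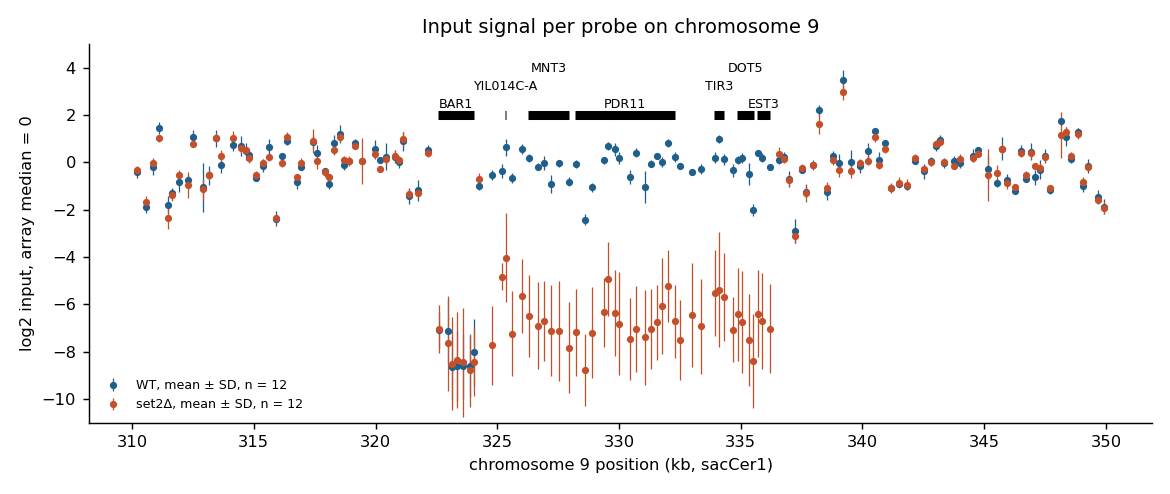
Input signal of each probe on part of chromosome 9 (x axis, position in kb; y axis, log2 input relative to the array median; points, mean of 12 arrays per strain; bars, SD), with the loci drawn as black bars. From 324768 to 336218 the probes lie near 0 in WT and far below it in set2Δ, and the BAR1 probes are low in both strains.

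In WT, acetylation was higher over promoters than over the middle of ORFs, and H3 was lower there. H3K9ac, a mark of active promoters, averaged 0.89 ± 0.04 (log2 IP over input, SD, n = 3) over 4693 promoters and 0.58 ± 0.02 over the 5' part of ORFs. It was -0.03 ± 0.01 in the middle part and 0.01 ± 0.02 in the 3' part. H3K56ac, carried by newly deposited histones, was highest over promoters (1.02 ± 0.11) and lower in the 5' (0.26 ± 0.07) and 3' (0.12 ± 0.05) parts. H4K12ac averaged 0.20 ± 0.01 over promoters and 0.21 ± 0.01 in the 5' part, against 0.01 ± 0.01 in both the middle and 3' parts. H3 was -0.67 ± 0.11 over promoters, -0.02 ± 0.03 in the 5' part, 0.11 ± 0.03 in the middle and 0.03 ± 0.03 in the 3' part.

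In set2Δ, acetylation over promoters and 5' ends fell relative to that of 3' ends. The question of this comparison is where along genes each acetylation differs between the strains. The H3K9ac promoter mean was -0.00 ± 0.07, and it differed from that of WT by -0.90. The 5' part differed by -0.52, the middle by 0.06 and the 3' part by 0.15. H3K56ac differed by -0.64 over promoters and -0.15 in the 5' part, and by 0.02 in the 3' part (exact permutation p = 0.8). H4K12ac differed by -0.41 over promoters, -0.22 in the 5' part and 0.12 in the 3' part. The H3 profile moved the other way in the 5' part, by 0.11, and by 0.08 over promoters (exact permutation p = 0.4). These values are relative to the median probe of each array. With arrays centred on probes outside ORFs the promoter changes were -0.11 for H3K9ac, -0.15 for H3K56ac and -0.09 for H4K12ac, the 5' changes turned to 0.27, 0.34 and 0.10, and the 3' changes were 0.93, 0.51 and 0.44. Of the probes outside ORFs 6840 lay in promoters, against 2769 further upstream, 1188 in 3' flanks and 453 further downstream. This centring thus holds the promoter change near 0 by construction, and a loss over promoters would appear as a gain over ORFs. Whether the 5' part lost acetylation therefore depends on the reference, and the differences between parts do not.

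The difference between the 3' and 5' parts of an ORF gave the gradient over 4036 ORFs. For H3K9ac it was -0.60 ± 0.03 (SD, n = 3) in WT and 0.14 ± 0.03 in set2Δ, a change of 0.74 ± 0.02 (SE). The H4K12ac gradient changed by 0.39 ± 0.01, from -0.23 ± 0.01 to 0.16 ± 0.02, and that of H3K56ac by 0.19 ± 0.01, from -0.12 ± 0.02 to 0.07 ± 0.02. The H3 gradient changed by -0.15 ± 0.01, from 0.06 ± 0.01 to -0.09 ± 0.01. Mean gradients were higher in set2Δ at 84.1% of the ORFs for H3K9ac, 79.6% for H4K12ac, 65.9% for H3K56ac and 32.5% for H3. All 3 set2Δ arrays lay above all 3 WT arrays at 61.4%, 41.6%, 28.0% and 3.8% of the ORFs in the same order, against 5% by chance in each direction. Two-sided exact permutation tests gave p = 0.1 for each gradient change, the smallest p that 3 against 3 arrays allow (adjusted p = 0.109 over 12 region tests).

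The difference between an ORF and its promoter, over 4181 genes, changed by 0.81 ± 0.06 (SE) for H3K9ac, 0.60 ± 0.07 for H3K56ac and 0.40 ± 0.06 for H4K12ac (exact permutation p = 0.1 each). For H3K56ac it was 0.29 with quantile normalization and 0.35 with arrays scaled to 1 median absolute deviation. For H3 the change was -0.04 ± 0.10 (exact permutation p = 0.8), and its sign depended on single arrays: it was 0.02 without WT replicate 3 and 0.03 without set2Δ replicate 1. Each acetylation was then set against H3. Arrays of 1 strain and number varied together, so both IPs of a number were relabelled as a unit, in all 20 ways. The gradient change differed from that of H3 by 0.89 ± 0.02 (SE) for H3K9ac, 0.54 ± 0.01 for H4K12ac and 0.34 ± 0.02 for H3K56ac, and the ORF minus promoter change by 0.84 ± 0.05, 0.43 ± 0.13 and 0.64 ± 0.14 in the same order (two-sided permutation p = 0.1 each, the smallest that 20 relabellings give).

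Among the arrays of 1 scan that held both strains, the gradient changed by 0.76 for H3K9ac (1 WT against 3 set2Δ arrays), 0.40 for H4K12ac (3 against 1) and -0.15 for H3 (3 against 1). The ORF minus promoter change within a scan was 0.77 for H3K9ac, 0.50 for H4K12ac and -0.16 for H3. For H3K56ac each strain was scanned apart, so strain and scan cannot be told apart in any H3K56ac value.

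**Figure D2:**
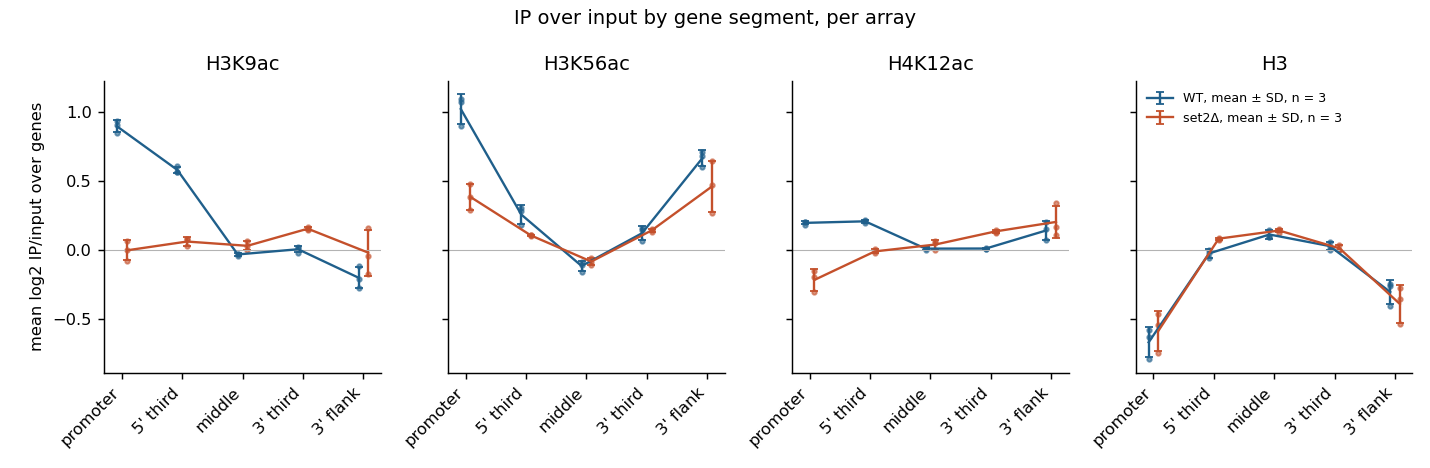
Mean log2 IP over input of promoters, the 3 parts of ORFs and 3' flanks (x axis) for each antibody (panels); lines join group means, bars are SD over 3 arrays and points are single arrays. In the H3K9ac panel the WT line falls from 0.89 at promoters to 0.01 in the 3' part, while the set2Δ line runs from -0.00 to 0.15.

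In set2Δ acetylation over long ORFs rose relative to that over short ORFs. ORFs were split by coding length into 4 classes of about equal size. In the class of the shortest ORFs (219 to 894 bp) mean H3K9ac differed by -0.67 ± 0.02 (SE) between the strains, and in that of the longest (2004 to 14733 bp) by 0.57 ± 0.03. Of the 1249 longest ORFs 76.9% were called higher in H3K9ac and 5.93% lower (limma), and of the 1252 shortest 2.56% were called higher and 76.6% lower. H4K12ac differed by -0.25 ± 0.01 in the shortest and 0.24 ± 0.01 in the longest class, and H3K56ac by -0.18 ± 0.06 and 0.13 ± 0.01. With arrays centred on probes outside ORFs the shortest class differed by 0.11 for H3K9ac, 0.07 for H4K12ac and 0.30 for H3K56ac, and the longest by 1.36, 0.55 and 0.62, so the decrease over short ORFs depends on the reference. H3 differed by 0.12 ± 0.02 in the shortest and -0.05 ± 0.02 in the longest class. The change of the longest minus the shortest class was 1.24 ± 0.04 for H3K9ac, 0.48 ± 0.02 for H4K12ac, 0.32 ± 0.06 for H3K56ac and -0.17 ± 0.02 for H3 (exact permutation p = 0.1 each). With quantile normalization the change of H3K56ac was 0.03, and with arrays scaled to 1 median absolute deviation that of H3K56ac was 0.06 and that of H3K9ac 0.68. The differences from the H3 change were 1.42, 0.66 and 0.49 for H3K9ac, H4K12ac and H3K56ac (permutation p = 0.1 each, over 20 relabellings). Within 1 scan the change was 1.27 for H3K9ac, 0.48 for H4K12ac and -0.19 for H3.

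**Figure D3:**
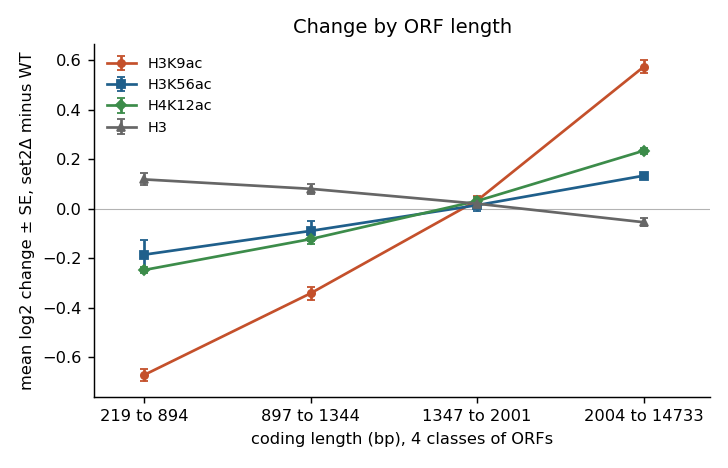
Mean log2 change from WT to set2Δ (y axis, with SE) of ORFs in 4 classes of coding length (x axis, bp), 1 line per antibody. The H3K9ac line climbs from -0.67 to 0.57, and the H3 line falls from 0.12 to -0.05.

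Changes of single ORFs are relative to the median probe of each array, and this reference mattered. With each array centred on its probes outside ORFs instead, all ORF changes moved by 0.78 for H3K9ac, 0.49 for H3K56ac, 0.32 for H4K12ac and -0.02 for H3. Most of these probes lie in promoters, so a loss over promoters alone would move ORF changes upwards in this way. Higher and lower therefore mean relative to the array median unless another reference is named. The medians over gene lists were also taken after subtracting the median of all 5006 ORFs tested. The sign of this difference changed under no other scaling for any called list of the 4 antibodies, except H3K56ac of the glycolysis list, but its size did: for H3K9ac it fell from -0.62 to as little as -0.11 at glycolysis, from -0.55 to -0.20 at ribosomal proteins, from 0.37 to 0.14 at ribosome biogenesis, from -0.38 to -0.15 at respiration, from -0.495 to -0.259 at meiosis, from 0.32 to 0.13 at subtelomeric ORFs, from 0.53 to 0.325 at G1/S and from 1.145 to 0.76 at cryptic initiation, and for H3K56ac from -0.54 to -0.21 at pheromone response and from 0.17 to 0.11 at subtelomeric ORFs.

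H3K9ac was compared between the strains to ask at which genes it differs. Its ratios were less spread in set2Δ, with a median absolute deviation of 0.76 to 0.87 per array against 1.40 to 1.47 in WT. A narrower range alone would raise the lowest WT values and lower the highest ones most. This was not separated from a change at the single genes and gene lists below. At NFT1, an ABC transporter gene (YKR103W, chromosome 11, 652836 to 656248), H3K9ac rose by 1.98 ± 0.08 (SE), from -1.79 ± 0.09 (SD, n = 3) to 0.20 ± 0.06 (adjusted p = 1.59e-13). At SCC2, the cohesin loader (YDR180W, chromosome 4, 821472 to 825762), it rose by 1.66 ± 0.09, from -1.79 ± 0.15 to -0.12 ± 0.19 (adjusted p = 5.65e-12). At FLO11, a flocculin (YIR019C, chromosome 9, 389590 to 393352), it rose by 1.63 ± 0.14 (adjusted p = 1.09e-09). Over all probes with a value, the retromer subunit VPS5 (1.80), the pyruvate decarboxylase PDC5 (1.66), the signal recognition particle receptor gene YDR292C (1.62), MIL1 (1.62) and YEL023C (1.85) completed the 8 largest increases. The largest decrease over these probes was at YPR078C (chromosome 16, 697381 to 698149), -2.28 ± 0.19, from 2.55 ± 0.15 to 0.28 ± 0.46 (adjusted p = 8.43e-10). The myosin light chain MLC1 (YGL106W, chromosome 7, 306746 to 307015) fell by 1.89 ± 0.12 (adjusted p = 2.92e-11). The other large decreases were at the sporulation gene SPO77 (-1.96), the dynactin subunits ARP10 (-1.92) and LDB18 (-1.80), the nitrogen repressor DAL80 (-1.87), RRT5 (-1.83) and PIR5 (-1.80). Since outlier spots were left out, some of these values compare different probes in the strains. Over probes with a value on all 6 arrays YPR078C changed by -1.75 ± 0.16 and MLC1 by -1.41 ± 0.13 (1 probe each), DAL80 by -1.60 ± 0.23, SPO77 by -2.01 ± 0.15, NFT1 by 2.05 ± 0.08 and SCC2 by 1.71 ± 0.10, and among ORFs with at least 2 such probes SPO77 had the largest decrease. Among these, SET5 (1.89 over such probes), SPT7 (1.76) and TOG1 (1.73) were in the 8 largest increases in place of FLO11, YDR292C and MIL1, and IZH4 (-1.97), RIF2 (-1.755) and PUT4 (-1.73) in the 8 largest decreases in place of YPR078C, MLC1 and DAL80; these 6 ORFs were named after their values were seen.

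Of the 5006 ORFs, 1554 were called higher and 2059 lower in H3K9ac (limma, two-sided, adjusted p under 0.05), 43.0% of the calls being higher. With arrays centred on probes outside ORFs 93.0% of the calls were higher, and with quantile normalization 54.0%. In 3598 of the ORFs a probe had no value on some H3K9ac array, and in 872 fewer probes had a value in set2Δ than in WT. Over probes with a value on all 6 arrays 3586 ORFs were called, 98 ORFs changed by over 0.5 from their value over all probes, and of the 3575 ORFs called with all probes that had a value there, 3536 moved the same way. At 71.7% of the ORFs the arrays of the strains did not overlap, against 10% by chance. With scan as a fixed block 2961 ORFs were called.

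Most genes known for cryptic internal initiation in set2 mutants gained H3K9ac inside their coding regions. Of the 7 measured members of this list, 5 rose and 2 did not pass the test (5 higher and 0 lower adjusted over the list alone), with a median change of 1.01 (camera adjusted p = 0.00461; adjusted p = 0.117 with an estimated correlation). Random lists of the same length had a median of 0.59, and the list lay at percentile 97.6 of them; adjusted for ORF length its median was 0.21 and no longer called (adjusted p = 0.195). VPS72, a subunit of the SWR1 remodeller (YDR485C, chromosome 4, 1424879 to 1426827), rose by 1.39 ± 0.14 (SE, adjusted p = 1.1e-08). The cohesin subunit SMC3 rose by 1.09, the cadmium transporter PCA1 by 1.02, the pheromone-pathway kinase STE11 by 1.01 and the TORC2 subunit AVO1 by 0.88. SPB4 (0.23, adjusted p = 0.075) and SYF1 (-0.05, adjusted p = 0.635) did not pass; over probes with a value on all 6 arrays they were at 0.38 (adjusted p = 0.00742) and 0.30 (adjusted p = 0.0106), and PCA1 at 0.65. In STE11 (YLR362W, chromosome 12, 849914 to 851880) the change was -0.17 in the 5' part, 1.59 in the middle and 1.49 in the 3' part. In PCA1 (YBR295W, chromosome 2, 792906 to 796466) it was 0.34, 1.06 and 1.89. Over probes with a value on all 6 arrays these changes were -0.34, 1.59 and 1.60 in STE11 and 0.34, 1.08 and 1.37 in PCA1. FLO8, the eighth member, is a pseudogene in the reference table and was outside the ORFs tested; its 10 probes changed by 0.95 (exact permutation p = 0.1).

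**Figure D4:**
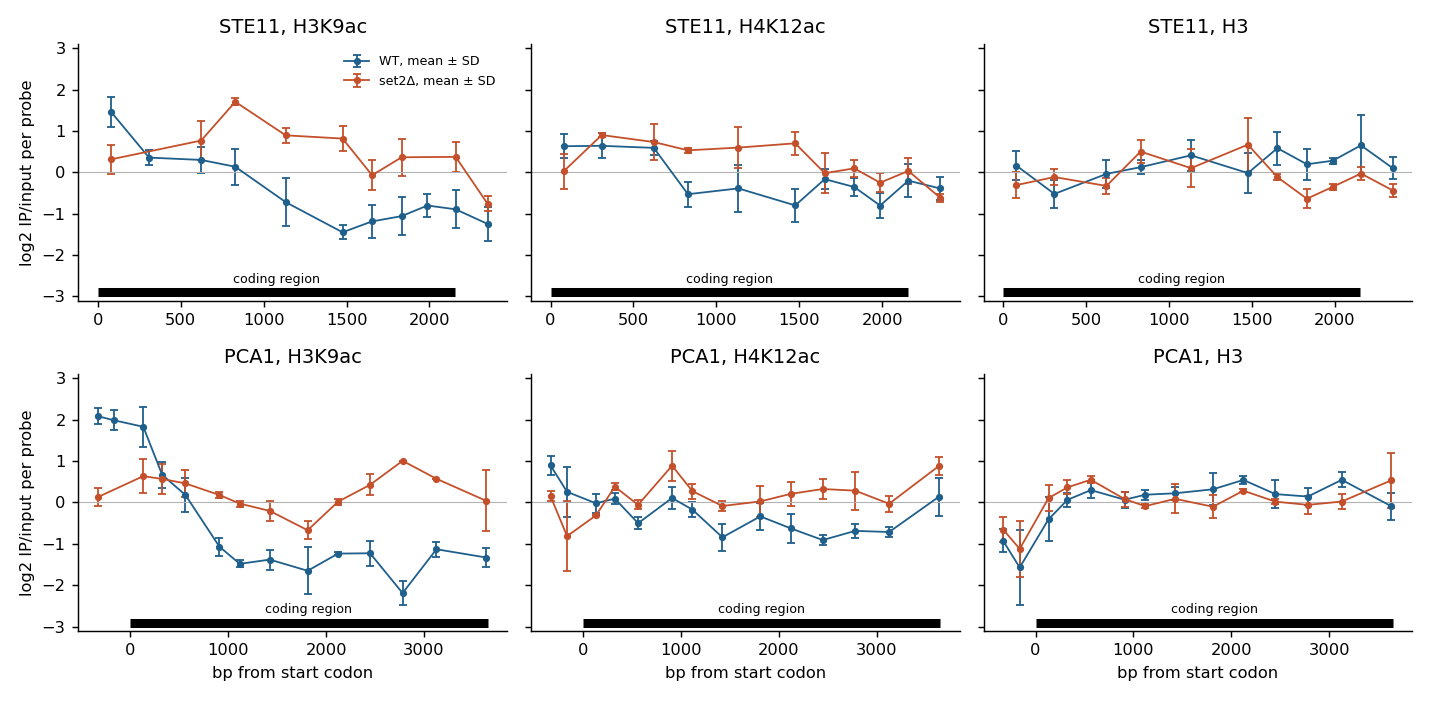
Log2 IP over input of each probe along STE11 and PCA1 (x axis, bp from the start codon; points, mean of the arrays with a value; bars, SD; black bar, coding region). At STE11 the H3K9ac means of the middle and 3' parts are higher by 1.59 and 1.49 in set2Δ.

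H3K9ac was lower in set2Δ at the ribosomal protein, glycolysis, meiosis and respiration lists, of which the first and the last hold short ORFs (median 842 and 691.5 bp). Ribosomal protein genes had a median change of -0.68, or -0.55 after subtracting the median of all ORFs, and 89 of 103 fell and none rose (93 and 0 adjusted over the list alone; camera adjusted p = 3.08e-09, and adjusted p = 0.0196 with an estimated correlation). RPL12B (-1.55), RPS22A (-1.39) and RPL31B (-1.29) had the largest changes. Random lists of the same length had a median of -0.58, and the list lay at percentile 4.22 of them; adjusted for ORF length its median was -0.22 and no longer called (adjusted p = 0.0649). The median of the list was 0.10 with arrays centred on probes outside ORFs, -0.27 with quantile normalization and -0.22 with arrays scaled to 1 median absolute deviation. In WT the 5' parts of ribosomal protein and glycolysis genes were high in H3K9ac (1.88 and 1.83), where a narrower range would lower values most. Glycolysis genes had a median of -0.75, with 11 of 16 lower and 0 higher, led by TDH2 (-1.42), TDH3 (-1.27) and PGK1 (-1.19) (camera adjusted p = 0.0272; adjusted p = 0.484 with an estimated correlation). This call was lost with quantile normalization (median -0.19, adjusted p = 0.258), with arrays scaled to 1 median absolute deviation (-0.13, adjusted p = 0.347), with loess (-0.40, adjusted p = 0.0763) and with probes marked on any array left out (-0.59, adjusted p = 0.0525), and the median was 0.03 with arrays centred on probes outside ORFs. Meiosis and sporulation genes had a median of -0.63, with 19 of 28 lower and 6 higher, the largest at DMC1 (-1.60), MEI4 (-1.47) and SSP1 (-1.20) (adjusted p = 0.0272, and adjusted p = 0.169 with an estimated correlation). With normexp background correction this call was lost (-0.41, adjusted p = 0.277) and SSP1 was at 0.04, the call was also lost with only probes well above background in both channels (-0.58, adjusted p = 0.0736), and with arrays centred on probes outside ORFs the median was 0.16. Respiration genes had a median of -0.51, with 15 of 20 lower, 1 higher, and examples ATP3 (-1.28), COX13 (-0.76) and ATP7 (-0.75) (adjusted p = 0.0272; adjusted p = 0.169 with an estimated correlation). Length-matched lists had a median of -0.57 beside that of the respiration genes, and adjusted for ORF length the list turned to 0.14 (adjusted p = 0.584), COX13 to 0.17 and ATP7 to 0.04, so its decrease was not kept. Its call was also lost with quantile normalization (-0.14, adjusted p = 0.181), with arrays scaled to 1 median absolute deviation (-0.175, adjusted p = 0.222), with loess (-0.30, adjusted p = 0.0914), with probes marked on any array left out (-0.45, adjusted p = 0.0525) and with at least 3 probes per ORF (-0.395, adjusted p = 0.106), and with arrays centred on probes outside ORFs the median was 0.27, ATP7 at 0.03 and COX13 at 0.02. The glycolysis and meiosis lists lay at percentile 0 of length-matched lists (median -0.15 each) and stayed called after the adjustment for ORF length. Over probes with a value on all 6 arrays RPL12B was at -1.13, DMC1 at -1.19 and SSP1 at -0.74, and RPS22A and TDH2 had no such probe.

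H3K9ac was higher in set2Δ at the chromatin factor, ribosome biogenesis, G1/S and subtelomeric lists. Chromatin factors had a median of 0.29, with 15 of 29 higher and 4 lower, led by the histone chaperone genes HIR3 (1.28), HPC2 (1.27) and SPT6 (1.17) (camera adjusted p = 0.00171; adjusted p = 0.051 with an estimated correlation). Ribosome biogenesis genes had a median of 0.24, with 18 of 39 higher and 5 lower, among them ERB1 (1.49), NOP14 (1.43) and UTP20 (1.13) (adjusted p = 0.00461, and adjusted p = 0.117 with an estimated correlation). The G1/S list had a median of 0.40, with 10 of 18 higher and 2 lower, led by the DNA ligase CDC9 (1.31), the polymerase POL2 (1.19) and the transcription factor SWI4 (0.96) (adjusted p = 0.0272; adjusted p = 0.117 with an estimated correlation). Subtelomeric ORFs had a median of 0.18, with 50 of 111 higher and 32 lower, with NFT1, the maltose transporter MAL11 (1.55) and the cell wall mannoprotein DAN4 (1.48) the largest (adjusted p = 0.0272, and adjusted p = 0.179 with an estimated correlation). Length-matched lists had medians of 0.20, 0.08, 0.03 and -0.22 in this order, and the lists lay at percentiles 75.27, 89.75, 98.15 and 100 of them, so the medians of chromatin factors and ribosome biogenesis were within the range of other ORFs of their length. Adjusted for ORF length the medians were 0.19, 0.09, 0.21 and 0.27, UTP20 was at -0.035 (adjusted p = 0.711), and the call of G1/S was lost (adjusted p = 0.0557), as it was with at least 3 probes per ORF (adjusted p = 0.0743). With quantile normalization the calls of ribosome biogenesis (0.16, adjusted p = 0.116) and subtelomeric ORFs (0.22, adjusted p = 0.181) were lost, as they were with arrays scaled to 1 median absolute deviation (0.15, adjusted p = 0.191, and 0.11, adjusted p = 0.221). Over probes with a value on all 6 arrays the subtelomeric median was 0.07 and not called (adjusted p = 0.0696), and it was not called with probes marked on any array left out (adjusted p = 0.0623), with at least 3 probes per ORF (adjusted p = 0.125) or with arrays centred on probes outside ORFs (adjusted p = 0.0572). Within the shared scan the medians were 0.99 for cryptic initiation, -0.66 for ribosomal proteins, -0.74 for glycolysis, -0.60 for meiosis, -0.54 for respiration, 0.49 for chromatin factors, 0.28 for ribosome biogenesis, 0.39 for G1/S and 0.20 for subtelomeric ORFs. With scan as a fixed block they were 0.99, -0.66, -0.92, -0.60, -0.54, 0.49, 0.28, 0.39 and 0.20. This block too sets WT replicate 3 alone against the set2Δ arrays, so it is no separate check.

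**Figure D5:**
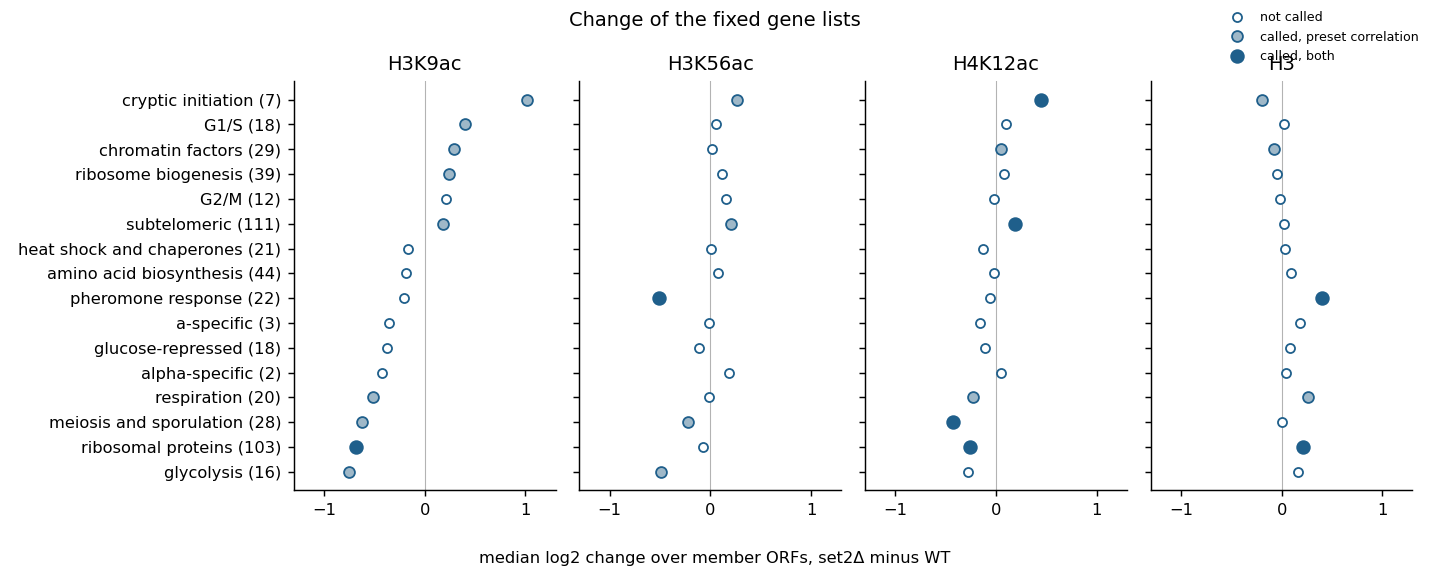
Median log2 change from WT to set2Δ (x axis) of the ORFs of each gene list (y axis, members in brackets), 1 panel per antibody; filled points passed camera with both the preset and the estimated correlation, grey points with the preset one alone. Pheromone response stands at -0.51 for H3K56ac and 0.40 for H3.

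H3K56ac, which marks histones placed on DNA since their synthesis, was compared in the same way, and its largest decreases were at short genes that were rich in it in WT. Its ratios were less spread in set2Δ, with a median absolute deviation of 0.50 to 0.64 per array against 0.86 to 0.90 in WT. A narrower range alone would lower the highest WT values most, and this was not separated from a change at these genes. The largest rise was at YFR057W, a subtelomeric ORF (chromosome 6, 269033 to 269339), by 2.02 ± 0.17 (SE), from 0.10 ± 0.12 (SD, n = 3) to 2.11 ± 0.11 (adjusted p = 1.22e-08). The splicing factor PRP4 (YPR178W, chromosome 16, 892514 to 893633) rose by 1.08 ± 0.12 (adjusted p = 6.64e-07). The G1 cyclin PCL1 (1.03), the small heat shock protein HSP26 (1.02), the replication factor PSF3 (1.01), RFU1 (1.00), AAD3 (0.99) and the tRNA splicing subunit SEN34 (0.94) followed. The largest decreases were at ARP10 (-2.26), ICS3 (-2.22), SIP18 (-2.20), UTP30 (-2.17), TRI1 (-2.17), YOR268C (-2.09), HBN1 (-2.06) and the phosphatase YCH1 (-2.05). ARP10 (YDR106W, chromosome 4, 667514 to 667801) went from 2.72 in WT to 0.46 in set2Δ (adjusted p = 2.91e-09).

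In H3K56ac 740 ORFs were called higher and 726 lower (limma, two-sided), 50.5% of them higher. The share higher was 94.8% with arrays centred on probes outside ORFs, 72.0% with no centring and 69.1% with quantile normalization, and the count was 715 with normexp background correction and 3865 with arrays centred on probes outside ORFs. At 42.6% of the ORFs the arrays of the strains did not overlap, against 10% by chance.

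Genes of the pheromone response fell in H3K56ac relative to other ORFs. Their median change was -0.51, and 15 of 22 fell and none rose (15 and 0 adjusted over the list alone; camera adjusted p = 5.01e-10, and adjusted p = 0.0181 with an estimated correlation). The a-specific gene ASG7 fell by 1.71, the nuclear fusion genes PRM3 and KAR5 by 1.64 and 1.44, and the adhesin genes AGA1 and FIG2 by 0.93 and 1.03; under quantile normalization PRM3 was at 0.07 and AGA1 at 0.19. The median of the list was -0.15 with quantile normalization (adjusted p = 0.0171), -0.26 with arrays scaled to 1 median absolute deviation (adjusted p = 0.000477) and -0.02 with arrays centred on probes outside ORFs. The promoters of 18 members went from 2.10 ± 0.19 (SD, n = 3) to 0.54 ± 0.14. Glycolysis genes had a median of -0.49, with 8 of 16 lower and 0 higher (9 lower adjusted over the list alone), among them TPI1 (-1.13), TDH2 (-1.04) and PGK1 (-0.89) (adjusted p = 0.000712; adjusted p = 0.329 with an estimated correlation), and under quantile normalization the median was 0.18 (adjusted p = 0.643), TDH2 was at 0.44 (adjusted p = 0.0326, called the other way) and PGK1 at 0.20. With arrays scaled to 1 median absolute deviation the call was lost (-0.08, adjusted p = 0.618), the median was -0.313 with normexp and -0.005 with arrays centred on probes outside ORFs. Meiosis and sporulation genes had a median of -0.22, with 10 of 28 lower and 2 higher, led by MEI4 (-1.24), DMC1 (-0.90) and REC114 (-0.82) (adjusted p = 0.00287; adjusted p = 0.119 with an estimated correlation), and with no centring the median was -0.11. Cryptic initiation genes had a median of 0.26, with PCA1 (0.51), STE11 (0.39) and AVO1 (0.38) higher and the other 4 not called (adjusted p = 0.016; adjusted p = 0.192 with an estimated correlation). Subtelomeric ORFs had a median of 0.20, with 35 of 111 higher and 9 lower, YFR057W, YHL042W (-1.25) and IRC4 (-1.12) changing most (adjusted p = 0.0054, and adjusted p = 0.181 with an estimated correlation). Among length-matched lists pheromone response and glycolysis lay at percentile 0, meiosis at 0.02, cryptic initiation at 90.85 and subtelomeric ORFs at 100. Adjusted for ORF length the call of cryptic initiation was lost (median 0.13, adjusted p = 0.119). The subtelomeric call was lost with arrays centred on probes outside ORFs (adjusted p = 0.0858), and the median was 0.12 with arrays scaled to 1 median absolute deviation.

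H4K12ac was compared between the strains in the same way. PDC5 (YLR134W, chromosome 12, 410931 to 412176) rose by 1.19 ± 0.14 (SE), from -0.12 to 1.06 (adjusted p = 8.64e-06), and FLO11 by 1.09 ± 0.14 (adjusted p = 1.05e-05). The flocculin FLO5 (1.20), DAN4 (1.13) and the mannoprotein TIR4 (1.01) also rose. At the nuclear pore subunit POM34 (1.14 ± 0.35) the change came from the 5' part, where WT arrays were spread widely (-1.21 ± 1.92, SD), and it was not called without WT replicate 1 (0.73, adjusted p = 0.122), without set2Δ replicate 3 (adjusted p = 0.0578) or with scan as a fixed block (adjusted p = 0.129). PDR11 (2.99 ± 0.70) and TIR3 (2.53 ± 0.77) had the largest values, but both lie in the chromosome 9 stretch whose input was far below the array median in set2Δ. The largest decreases were at the meiotic genes CSM4 (-1.19) and HOP2 (-1.17), at YER085C (-1.15), IZH4 (-1.07), DAL80 (-1.05), CAX4 (-1.03), the sporulation gene PFS1 (-1.02) and the spore wall gene CRR1 (-1.01). HOP2 (YGL033W, chromosome 7, 435669 to 436046) fell from 0.20 in WT to -0.97 in set2Δ (adjusted p = 0.000358).

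In H4K12ac 846 ORFs were called higher and 712 lower (limma, two-sided), 54.3% of them higher; 97.6% of the calls were higher with arrays centred on probes outside ORFs and 64.4% with no centring. At 46.1% of the ORFs the arrays of the strains did not overlap, against 10% by chance. With scan as a fixed block 691 ORFs were called (436 higher, 255 lower).

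Cryptic initiation genes rose in H4K12ac, 6 of 7 passing the test (7 adjusted over the list alone) with a median of 0.45 (camera adjusted p = 0.00036, and adjusted p = 0.0325 with an estimated correlation). PCA1 (0.60), STE11 (0.50), VPS72 (0.48), AVO1 (0.45), SMC3 (0.43) and SYF1 (0.24) rose, and SPB4 was at 0.29 (adjusted p = 0.0621). Meiosis and sporulation genes had a median of -0.43, with 14 of 28 lower and 1 higher (16 and 1 adjusted over the list alone), among them SPO19 (-0.74), SPR28 (-0.72) and MER1 (-0.57) (adjusted p = 0.000517, and adjusted p = 0.0325 with an estimated correlation). Ribosomal protein genes had a median of -0.26, or -0.21 after subtracting the median of all ORFs, with 27 of 103 lower and 1 higher, led by RPS10B (-0.61), RPL31A (-0.60) and RPS18B (-0.59) (adjusted p = 2.04e-06, and adjusted p = 0.0325 with an estimated correlation). Subtelomeric ORFs had a median of 0.19, with 37 of 111 higher and 6 lower, DAN4, MAL11 (0.98) and NFT1 (0.96) being the largest (adjusted p = 6.2e-05, and adjusted p = 0.0325 with an estimated correlation). Chromatin factors had a median of 0.06, or 0.10 after subtracting the median of all ORFs, with 10 of 29 higher and 0 lower, including the histone regulators HIR3 (0.71), HIR2 (0.66) and HIR1 (0.55) (adjusted p = 0.0134; adjusted p = 0.0881 with an estimated correlation). Respiration genes had a median of -0.23, with 4 of 20 lower and 1 higher, including ATP5 (-0.63), SDH3 (-0.58) and SDH4 (-0.57) (adjusted p = 0.0218; adjusted p = 0.133 with an estimated correlation). With scan as a fixed block the medians were 0.49, -0.47, -0.31, 0.23, 0.05 and -0.23 in this order. They equal those within the shared scan by construction, since both set set2Δ replicate 1 alone against the WT arrays. Among length-matched lists they lay at percentiles 97.04, 0, 4.31, 100, 36.33 and 28.46, so chromatin factors (length-matched median 0.08) and respiration (-0.19) changed like other ORFs of their length. Adjusted for ORF length the calls of cryptic initiation (0.19, adjusted p = 0.0625), ribosomal proteins (-0.10, adjusted p = 0.206), chromatin factors (0.02, adjusted p = 0.231) and respiration (-0.12, adjusted p = 0.49) were lost, and with at least 3 probes per ORF those of chromatin factors and respiration (adjusted p = 0.053 each). With arrays centred on probes outside ORFs the medians of meiosis, ribosomal proteins and respiration were -0.11, 0.06 and 0.09.

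H3 itself rose in set2Δ over mating genes that were depleted of H3 in WT. FIG2, an adhesin of mating cells (YCR089W, chromosome 3, 267477 to 272247), rose by 2.01 ± 0.12 (SE), from -2.74 in WT to -0.73 in set2Δ (adjusted p = 3.79e-10). The agglutinin anchor AGA1 (YNR044W, chromosome 14, 703675 to 705679) rose by 1.11 ± 0.14 (adjusted p = 7.92e-05), FIG1 by 0.80 and PRM4 by 0.75. The cell wall genes SED1 (0.96) and HSP150 (0.81), UTH1 (0.95) and its neighbour YKR041W (1.55) also gained H3. The 6 ORFs with less H3 were LRO1 (-0.61), RCO1 (-0.59), PUL4 (-0.43), RAD50 (-0.40), RBH2 (-0.36) and MIL1 (-0.36). These decreases rested on single arrays: 0 ORFs were called lower without WT replicate 1 or without set2Δ replicate 2, and 1, RCO1, without WT replicate 2 or without set2Δ replicate 1. RCO1 encodes a subunit of the Rpd3S deacetylase, which binds nucleosomes methylated by Set2.

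H3 calls were few: 32 ORFs higher and 6 lower (limma, two-sided; 550 and 314 at an unadjusted p under 0.05). At 24% of the ORFs the arrays of the strains did not overlap, against 10% by chance. With no centring 58.1% of the calls were higher, against 84.2%. The count rested on single arrays, falling to 7 without WT replicate 1 or 2, to 5 without set2Δ replicate 1 and to 6 without set2Δ replicate 2, and was 5 (5 higher and 0 lower) with scan as a fixed block.

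Pheromone-response genes gained H3 as a group. Their median change was 0.40, with 8 of 22 higher and none lower (16 and 0 adjusted over the list alone; camera adjusted p = 6.51e-17, and adjusted p = 0.00147 with an estimated correlation). The median of the list lay at percentile 100 of random lists matched for length. It was 0.49 with scan as a fixed block and within the shared scan, which both rest on set2Δ replicate 1 alone for that strain. Promoters of 18 members went from -2.40 ± 0.30 (SD, n = 3) to -1.66 ± 0.35. Ribosomal protein genes had a median of 0.21, with 4 of 103 higher and none lower (17 and 0 adjusted over the list alone), including RPL36B (0.61) and RPL5 (0.58), while RPS21B (0.56, adjusted p = 0.108) was not called (camera adjusted p = 1.76e-08, and adjusted p = 0.0162 with an estimated correlation). Respiration genes had a median of 0.26, with QCR6 (0.57) higher and the other members, such as ATP3 (0.57, adjusted p = 0.132) and ATP4 (0.37, adjusted p = 0.14), not called (adjusted p = 0.00604; adjusted p = 0.0765 with an estimated correlation). Cryptic initiation genes had a median of -0.20 with 0 of 7 called, AVO1 being at -0.33 (adjusted p = 0.0567) and VPS72 at -0.32 (adjusted p = 0.226) (camera adjusted p = 0.00572; adjusted p = 0.0765 with an estimated correlation). Chromatin factors had a median of -0.07, with RCO1 lower and RTT109 (-0.33, adjusted p = 0.251) and CTR9 (-0.30, adjusted p = 0.352) not called (adjusted p = 0.00768; adjusted p = 0.0765 with an estimated correlation). With scan as a fixed block these medians were 0.21, 0.19, -0.22 and -0.10, equal by construction to those within the shared scan. Among length-matched lists they lay at percentiles 100, 99.69, 0.99 and 7.66. Adjusted for ORF length the calls of respiration (0.17, adjusted p = 0.0962), cryptic initiation (-0.17, adjusted p = 0.101) and chromatin factors (-0.05, adjusted p = 0.119) were lost, and with at least 1 probe per ORF that of respiration (adjusted p = 0.0682).

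Acetylation was then compared with H3, as the change of the mark minus the change of H3, to separate the mark from the amount of nucleosomes. H3K9ac relative to H3 rose most at NFT1 (2.21 ± 0.12, SE), SCC2 (1.99), MIL1 (1.97) and VPS5 (1.97), and fell most at YPR078C (-2.55), MLC1 (-2.19), NAT4 (-2.18) and ARP10 (-2.11). Over probes with a value on all arrays of an IP YPR078C was at -2.02, MLC1 at -1.72 and NAT4 at -2.21. H3K56ac relative to H3 rose most at YFR057W (2.23), PRP4 (1.50), AAD3 (1.28) and PCL1 (1.25). It fell most at FIG2 (-3.04 ± 0.17, adjusted p = 9.52e-11), ARP10 (-2.46), the deacetylase HOS2 (-2.45) and GSR1 (-2.43). H4K12ac relative to H3 rose most at FLO11 (1.39), FLO5 (1.28), DAN4 (1.25) and PDC5 (1.19), and fell most at YKR041W (-2.16), FIG2 (-1.46), YER085C (-1.35) and LOA1 (-1.28). YKR041W was at 0.03 with normexp background correction.

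Pheromone-response genes had lower acetylation relative to H3 for every mark. For H3K56ac the median was -0.91 with 19 of 22 lower, for H4K12ac -0.53 with 12 lower and for H3K9ac -0.59 with 14 lower and 1 higher (camera adjusted p = 2.21e-15, 2.95e-06 and 0.0117; adjusted p = 0.00241, 0.0321 and 0.205 with an estimated correlation). The changes of the list in H3K9ac (median -0.205, adjusted p = 0.702, with 5 higher and 9 lower) and in H4K12ac (median -0.063, adjusted p = 0.73, with 3 higher and 3 lower) were not called, so for these marks the decrease relative to H3 goes with the rise of H3. With arrays centred on probes outside ORFs the medians relative to H3 were -0.40 for H3K56ac, -0.19 for H4K12ac and 0.22 for H3K9ac. With normexp background correction the calls for H3K9ac (adjusted p = 0.0965) and H4K12ac (adjusted p = 0.0898) were lost, and that for H3K9ac also with the median over probes (adjusted p = 0.0684). With quantile normalization the median for H3K56ac was -0.53 and that for H4K12ac -0.29. The cryptic initiation genes stood at 1.21 with 6 of 7 higher for H3K9ac, 0.54 with 4 higher for H3K56ac and 0.63 with 6 higher for H4K12ac (camera adjusted p = 0.00171, 0.00132 and 2.87e-05; adjusted p = 0.0767, 0.114 and 0.0251 with an estimated correlation). Adjusted for ORF length the call for H3K9ac was lost (median 0.34, adjusted p = 0.0659). Relative to H3, 1336 ORFs were higher and 1905 lower in H3K9ac, 569 and 672 in H3K56ac, and 660 and 535 in H4K12ac (limma, two-sided). The share of higher calls was 41.2%, 45.9% and 55.2%. Centring on probes outside ORFs made it 92.0% for H3K9ac and 93.4% for H3K56ac, and gave 1479 higher and 38 lower ORFs for H4K12ac. With no centring the shares were 70.3% for H3K56ac and 77.8% for H4K12ac, and with quantile normalization 52.0%, 63.4% and 66.7%. For H4K12ac, pairing each array with the H3 array of its strain and number gave 2345 calls and a scan block 278, against 1195.

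Across ORFs the changes of the acetylations went together, least so for H3K56ac with H4K12ac. Of the ORFs called higher, 785 were shared by H3K9ac and H4K12ac, against 262.6 for independent lists, and 531 by H3K9ac and H3K56ac, against 229.7. The numbers for lower ORFs were 614 against 292.9 and 620 against 298.6. H3K56ac and H4K12ac shared 382 higher ORFs against 125.1 and 239 lower ORFs against 103.3. The numbers for independent lists take no account of ORF length, with which the calls went. Of the longest class 76.9% were called higher in H3K9ac and 47.1% in H4K12ac, against 2.56% and 1.04% of the shortest. Part of the sharing thus goes with length, and how much was not separated. Correlations of the changes across ORFs, taken between arrays of different replicate numbers, were 0.68 to 0.76 for H3K9ac with H4K12ac, 0.48 to 0.57 for H3K9ac with H3K56ac, 0.23 to 0.42 for H3K56ac with H4K12ac and -0.42 to -0.26 for H3K9ac with H3. ORFs are not independent replicates, so no p is given for these.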

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

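The tests of the nonspecific DNA in the IPs, those within a scan, the relabelling by number and all tests of the chromosome 9 stretch were chosen after seeing the data, and the others before.

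In the 3' minus 5' gradient and in long minus short ORFs, but not in ORF minus promoter, each acetylation and H3 changed in opposite directions: all 3 set2Δ arrays lay on 1 side of all 3 WT arrays for the mark and on the other side for H3. For the gradient the difference was 0.889 for H3K9ac, 0.338 for H3K56ac and 0.535 for H4K12ac, and for long minus short ORFs 1.418, 0.492 and 0.656 (permutation p = 0.1 each, the smallest that 20 relabellings give, so no test of these differences that could pass 0.05 was run). More nonspecific DNA in the set2Δ IPs would raise the ratio at mitochondrial probes, which carry no histones. It differed in set2Δ by -1.836 for H3K9ac, -2.705 for H3K56ac and -1.647 for H4K12ac, and by 0.235 for H3 (set2Δ SD 0.993). Mitochondrial input was higher in set2Δ, 2.364 against 1.841 for H3K9ac, 2.893 against 2.146 for H3K56ac and 2.473 against 2.014 for H4K12ac. The acetylation IPs of the strains thus also differed at probes without histones, and why was not tested. A compressed range of ratios regardless of position would leave no difference between probes of 1 WT level. Yet among these the change was higher in the 3' than in the 5' part by 0.422, 0.188 and 0.339. Without such matching the gradient changes were 0.742, 0.192 and 0.389. H3K9ac ratios were less spread in set2Δ, with a median absolute deviation of 0.76 to 0.87 per array against 1.40 to 1.47 in WT. Long minus short ORFs were not matched for level, so a compressed range stays open there. Their change was 0.679 for H3K9ac with arrays scaled to 1 median absolute deviation, and 0.032 for H3K56ac with quantile normalization.

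Within the arrays of 1 scan the gradient change was 0.756 for H3K9ac and 0.399 for H4K12ac, which a difference between scans would not give. For H3K56ac 0 scans held both strains, so a difference between scans and one between strains cannot be told apart. For H3K9ac and H4K12ac the values are consistent with an effect of SET2 on where acetylation lies along genes, which stays a hypothesis and was not tested, since set2Δ also differed from WT in a stretch of chromosome 9; a set2Δ strain with that stretch intact would test it.

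Pheromone-response ORFs were lower in H3K56ac relative to H3 by a median of -0.911, a difference between the change of the mark and that of H3 (camera adjusted p = 2.21e-15, and adjusted p = 0.00241 with an estimated correlation). The median was -0.402 with arrays centred on probes outside ORFs and -0.531 with quantile normalization. A change of the input DNA at these genes would need the input to move by as much, and its median change was -0.027. Length does not account for the H3 part, since the list stood at percentile 100 of random lists of matched length. A weaker response of set2Δ cells to the pheromone may underlie both changes, and it was not tested, as expression was not analysed here. The labels also name a-factor, to which MATa cells such as BY4741 do not respond. In WT the promoters of 18 list members were at -2.40 for H3 and 2.10 for H3K56ac, against -0.67 and 1.02 over all promoters. All cultures carry the same treatment in the labels, so these values do not tell whether WT cells responded. For the H3K56ac part, scan and strain cannot be told apart, as 0 scans held both strains. H3K56ac ratios were also less spread in set2Δ, and a narrower range would lower genes high in WT most. The H3K56ac median of the list itself was -0.15 with quantile normalization and -0.26 with arrays scaled to 1 median absolute deviation. Promoters of glycolysis genes, at 3.53 in WT, changed by -2.09 in H3K56ac, against -1.55 at those of the pheromone list, so the decrease was not particular to this list.

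In the input DNA, which the comparisons of the strains use only as a denominator, a stretch of chromosome 9 was lower in set2Δ by a median of -6.69. Many set2Δ spots there were not well above background, so the size of this difference is uncertain. A fault on single arrays would spare some set2Δ arrays, but the highest mean among them was -3.96. Failing probes would be low in WT too, where the lowest mean was -0.46. The search took only probes lower in set2Δ than in WT, so probes failing in both strains could not enter the stretch. A loss of this stretch from the set2Δ strain, beside the BAR1 locus that is low in both strains, may explain these values, and when it arose was not tested. EST3, a telomerase subunit, lies in the stretch. The median input of subtelomeric Y' elements differed by 0.245 between the strains, with 9 of 13 loci higher in set2Δ. How far amplified Y' elements would raise the input was not measured, so this value does not decide whether they were amplified.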

How the results depend on the processing

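The handling of marked spots, the restriction to probes with a value on all arrays of an IP, the blocks and subsets by scan, the adjustment for ORF length and every alternative for the WT profile and the strain check were chosen after seeing the data. Where a value moved, the cause was not tested.

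The gradient, ORF minus promoter and length changes of the 3 acetylations kept their direction under all alternatives run. Some of these could not move them: no centring and centring on probes outside ORFs shift all probes of an array alike. Taking set2Δ minus WT within a replicate number leaves the means as they are, and the series table nearly repeats the processed ratios. The gradient change ranged from 0.496 to 0.825 for H3K9ac, 0.149 to 0.232 for H3K56ac and 0.371 to 0.579 for H4K12ac, the ORF minus promoter change from 0.585 to 1.02, 0.293 to 0.667 and 0.357 to 0.505, and the length change from 0.679 to 1.441, 0.032 to 0.318 and 0.388 to 0.755 in the same order. For H3K56ac the length change was 0.032 and the ORF minus promoter change 0.293 with quantile normalization, and 0.058 and 0.353 with arrays scaled to 1 median absolute deviation, which gave 0.679 for the length change of H3K9ac. The number of called lists ranged from 36 to 54 of 112.

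With normexp the calls were 715 for H3K56ac, 72 for H3 and 620 for H3K56ac relative to H3, SSP1 (H3K9ac) was at 0.042, STE2 (H3K9ac) at 0.024 and YKR041W (H4K12ac relative to H3) at 0.029. WT gradients were -0.679 for H3K9ac, -0.359 for H4K12ac and 0.087 for H3, WT ORF minus promoter -0.755 for H3K9ac and -0.179 for H4K12ac, and the SET2 input difference -1.92. With loess the calls were 940, 22 and 813 for H3K56ac, H3 and H3K56ac relative to H3, WT gradients -0.379 (H3K9ac) and -0.092 (H3K56ac), and WT ORF minus promoter -0.509, -0.677 and -0.126 for H3K9ac, H3K56ac and H4K12ac.

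Centred on probes outside ORFs, calls were 3865 for H3K56ac, 16 for H3 and 2902 for H3K56ac relative to H3, and H3K9ac was 0.03 at ATP7, 0.024 at COX13, 0.041 at FBP1 and 0.424 at STE2. Scaled to 1 median absolute deviation, calls were 930 for H3K56ac and 642 relative to H3, and STE6 (H3K9ac) was at -0.254. With quantile normalization calls were 18 for H3 and 677 for H3K56ac relative to H3, H3K56ac was 0.188 at AGA1, 0.204 at PGK1, 0.067 at PRM3, 0.442 at TDH2 and 0.177 for the glycolysis list, and the H3 ORF minus promoter change was 0.022.

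With the median over probes calls were 867 for H3K56ac, 8 for H3, 661 for H3K56ac relative to H3 and 674 for H4K12ac relative to H3. Adjusted for length they were 770 for H4K12ac, 18 for H3, 2049 for H3K9ac relative to H3 and 365 for H4K12ac relative to H3, and H3K9ac was 0.036 at ATP7, -0.442 at BUD4, 0.165 at COX13, -0.279 at STE6, -0.035 at UTP20 and 0.143 for the respiration list. With only the arrays compared 5 ORFs were called for H3.

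With replicate number as a fixed block 83 ORFs were called for H3, although the numbers do not pair the strains. Pairing mark and H3 of 1 strain and number gave 2345 calls for H4K12ac relative to H3, and a random block for strain and number 1817 (consensus correlation 0.265). With scan as a fixed block calls were 691 for H4K12ac, 5 for H3 and 278 for H4K12ac relative to H3, and with scan as a random block 286 for H3 (consensus correlation -0.162).

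Leaving out 1 array gave 3413 to 3511 calls for H3K9ac, 1072 to 1483 for H3K56ac, 1161 to 1271 for H4K12ac and 5 to 50 for H3. The H3 count was 7 without WT replicate 1 or 2, 5 without set2Δ replicate 1 and 6 without set2Δ replicate 2. Relative to H3 the ranges were 3052 to 3188, 1029 to 1279 and 932 to 1084, and 47 to 54 lists were called. Gradient changes were 0.728 to 0.759, 0.185 to 0.202, 0.384 to 0.398 and -0.153 to -0.141 for H3K9ac, H3K56ac, H4K12ac and H3. In the same order ORF minus promoter changes were 0.761 to 0.860, 0.548 to 0.652, 0.344 to 0.444 and -0.114 to 0.029 (H3 at 0.015 without WT replicate 3 and 0.029 without set2Δ replicate 1), and length changes 1.223 to 1.276, 0.276 to 0.373, 0.465 to 0.492 and -0.183 to -0.162. WT gradients were -0.618 to -0.591, -0.131 to -0.114, -0.234 to -0.224 and 0.055 to 0.066, WT ORF minus promoter -0.729 to -0.690, -0.953 to -0.901, -0.143 to -0.133 and 0.657 to 0.734, and the SET2 input difference -6.90 to -6.44.

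Of 4262 values of named genes under the other alternatives, 4012 kept direction and side of the threshold, 200 no longer passed, 33 newly passed and 17 reversed, and of 2208 list values 2073, 82, 51 and 2 did, where the direction of a list is that of camera against all other ORFs. The medians themselves took the other sign in 16 of 1007 values of called lists, 12 of them with arrays centred on probes outside ORFs. The share of spots well above background, at least 96.1% per array, limits values at the deleted and missing loci. Slide as a block and random blocks or trend for camera were not run. Alternatives that give no H3K56ac value were those within a scan, as no scan held both strains.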

Other observations

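Several gene lists did not pass the camera test for H3K9ac although single members changed. Heat shock and chaperone genes had a median of -0.17, with HSP10 (-1.64), the small heat shock proteins HSP26 (-1.10) and HSP42 (-0.86) lower (camera adjusted p = 0.783); HSP10 was at -1.01 over probes with a value on all 6 arrays. Glucose-repressed genes had a median of -0.38, with the malate synthase MLS1 (-1.03) and the gluconeogenic FBP1 (-0.74) lower and the galactokinase GAL1 (0.73) higher (adjusted p = 0.331); over probes with a value on all 6 arrays MLS1 was at -0.54, and with arrays centred on probes outside ORFs FBP1 was at 0.041. Amino acid biosynthesis genes had a median of -0.19, with LYS2 (1.06) higher and ILV6 (-0.98) and SER2 (-0.96) lower (adjusted p = 0.374). G2/M genes had a median of 0.22, with EGT2 (1.44), BUD4 (0.46) and CDC20 (0.42) higher (adjusted p = 0.0643); adjusted for ORF length BUD4 was at -0.442 (adjusted p = 4e-05).

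Of the mating-type lists, the a-specific genes ASG7 (-1.23) and STE2 (-0.36) were lower and the transporter STE6 (0.56) higher in H3K9ac, with a median of -0.36 (camera adjusted p = 0.783). The directions of STE2 and STE6 depended on the processing: STE2 was at 0.424 (adjusted p = 0.0254) with arrays centred on probes outside ORFs and 0.024 with normexp, and STE6 at -0.254 (adjusted p = 0.0339) with arrays scaled to 1 median absolute deviation and -0.279 (adjusted p = 0.0153) adjusted for ORF length. The alpha-specific a-factor receptor STE3 (-1.31) was lower and the agglutinin SAG1 (0.47) higher, with a median of -0.42 (adjusted p = 0.636). FLO8, outside the ORFs tested, was at 0.55 for H3K56ac, 0.51 for H4K12ac (exact permutation p = 0.1 each) and -0.11 for H3 (exact permutation p = 0.4). A second interval low in the input of both strains, over SRD1 and MAK32 on chromosome 3 (148727 to 151480), was at -8.18 ± 1.17 (SD, n = 12) in WT and -8.27 ± 1.59 in set2Δ, and was singled out after its values were seen.

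Other splits of the arrays were counted for the numbers of called ORFs. For each IP the 10 splits of 6 arrays are too few for a share under 0.05: the real split called 3613 ORFs for H3K9ac, 1466 for H3K56ac, 1558 for H4K12ac and 38 for H3, and the highest of the other splits 0, 0, 1 and 0. Relative to H3, the arrays of 1 strain and number were kept together, which again leaves 10 splits, too few: the real split called 3241, 1241 and 1195 ORFs for H3K9ac, H3K56ac and H4K12ac, and the highest of the others 0 for each. All other splits put both strains into each group, so differences between the strains widened the spread within groups. Their low counts were thus built in and do not measure false calls.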
